A study of Homo sapiens with 15 samples.

How the data were processed

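HEK293FT cells, a fast-growing derivative of a human embryonic kidney cell line, were studied with polyA RNA sequencing after CRISPR activation. Per the labels' protocols, cells received dCas9-VP64, an MS2-p65-HSF1 activator and a pool of 5 guide RNAs. The guides were placed 50 to 450 bp upstream of the start site of a long non-coding RNA, or had non-targeting sequence. Puromycin at 2 ug/mL was added at 24 hours and RNA was taken at 48 hours. Libraries were made with a strand-preserving kit in biological triplicates, per the labels' protocols.

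The 15 libraries form 5 groups of 3, taken from their titles and target labels. For 2 of the 5 groups the title and the target label carry different TrEx numbers. The libraries titled trex8168 are labelled as targeting TrEx5008, and those titled trex5008 as targeting TrEx8168. The columns of the table use the spelling of the titles, so groups are named here by title and the conflict was not settled.

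Per the submitters' processing notes, Bowtie2 2.2.1, STAR 2.5.1b, bedtools, Cufflinks, DESeq and DESeq2 1.14.1 were used with the builds hg19 and GRCh37, with no role or order given. The strand setting of the counting is not given in the sources used here, so overlapping and antisense loci are uncertain. Reads can also be split between pseudogenes and their parent genes. The table analysed holds 3 kinds of value. The deposited signal columns are the authors' mean normalised counts per group and over the 15 libraries. The deposited log2 fold changes compare each target group with control and are smaller in size than the log2 ratio of the means in all rows called at 0.05. The deposited p-value columns hold adjusted p, and the authors' call columns equalled an adjusted p under 0.1 in each comparison, with 0 mismatches. The table lists 11230 rows, and every row has an adjusted p under 0.1 in at least 1 comparison. Genes outside the list were not analysed here, so there is no genome-wide background. Of the listed rows, 7447 are annotated as protein-coding and 2831 carry no annotated type; 3036 are named only by a locus identifier.

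Values per library, standard errors, raw p-values and library totals were not used here. Depth is therefore unknown, no SD is given, and no count model was fitted, although one had been planned for counts per library. The planned fallback was used: the authors' adjusted p under 0.05 was counted as given in each of the 4 comparisons. Adjustment over a list alone needs raw p-values and could not be made, nor could a correlation between genes be estimated from residuals.

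A total of 27 gene lists were fixed before the data were examined, covering neural and pluripotency markers, stress responses, signalling targets, cell cycle, metabolism, matrix, histones, ribosome and respiratory chain. Lists with at least 3 listed rows were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the deposited log2 fold change against the other listed rows. The planned statistic was a Wald value or a fold change over its standard error, which the listed columns do not hold, so the fold change itself was used and signed log10 of the adjusted p was tried beside it. The preset correlation was 0.01, and Benjamini-Hochberg adjustment was made over the lists of a comparison. On simulated lists of 10 genes built from the trex4039 values, 2 of 5 lists shifted by 0.3 and 0 of 20 unshifted lists were called.

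Genes named in the text follow a rule fixed before the data were examined. It takes the targeted RNAs, their 5 nearest tested genes within 500 kb, and the 8 largest rises and 8 largest falls per comparison. These are ranked by log2 fold change among rows with a gene name, a mean of at least 50 and an adjusted p under 0.05. It adds 3 called members of each called list and 8 genes called alike in all 4 comparisons. The table does not pair TrEx numbers with loci, so targeted RNAs are not identified. The most strongly risen row not annotated as protein-coding stood in as the centre for neighbouring genes, a choice made after its values were seen. Other genes named outside the rule were also chosen after their values were seen.

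Differences between targets were tested for rows called in both comparisons. Raw p-values were recovered from rank and adjusted p, which gave approximate standard errors; the number of tests was set to the listed rows with an adjusted p, or to 69629, the highest locus number. The covariance from shared controls was set to 0, or to 0.5 of the product of both errors as an alternative. In a simulated pair of comparisons with the covariance set to 0, this recovered 99.7% of 298 genes that differed and called 0 of 2976 that did not. With the share of 0.5, 100% were recovered. Of the genes that did not differ, 0.37% were then called with the true number of tests and 0.17% with the number of listed rows. The simulated differences were larger than the median called change of any comparison (at most 0.45), so recovery of smaller differences is not shown. The covariance expected from shared controls was simulated from the same approximate errors, a step added after the data were seen. Overlaps of calls were set beside independent lists and beside 100 simulations of unchanged groups against shared controls, for pairs and for all 4 comparisons. Independent lists were taken over the listed rows tested in the comparisons at hand. Each listed row has an adjusted p under 0.1 in at least 1 comparison, so this background leaves out rows called nowhere. That raises the overlap given for independent lists. In the simulations the highest and lowest rows were called by rank in the observed numbers. Truly unchanged groups would have few calls, so the simulated overlaps are not what shared controls alone would yield.

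Transcript GC content came from GENCODE v29 (GRCh38) by gene name, including older names from a RefSeq gene table; no coordinates were taken from it. Of the protein-coding rows, 6416 (86.2%) had a value. Of other annotated rows 44.2% did, too few for a check by gene, so a first planned check on them by gene was dropped before any value of its replacement, a check by chromosome, was computed. That one used a two-sided permutation test with 100000 permutations. The GC trend was fitted by lowess with a span of 0.5 in statsmodels 0.14.6; other statistics used scipy 1.17.1 under Python 3.11.15. Coordinates are 1-based on hg19, as the deposited rows give them after adding 1 to the start. Log2 ratios of means used a pseudocount of 1. Alternatives were other thresholds, a mean filter, other windows, protein-coding rows, rows with a GC content, removal of the GC trend and another list statistic.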

Results

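RNA was sequenced from HEK293FT cells in which 1 of 4 TrEx long non-coding RNAs was targeted for activation with dCas9-based activators, or which received non-targeting guides. TrEx RNAs are long non-coding RNAs with transient expression during the differentiation of cortical neurons. The design asks which genes respond in each of the 4 target groups relative to the non-targeting control. Each of the 5 groups had 3 libraries, made as biological triplicates. The deposited table gives group means, fold changes and adjusted p-values without a spread, so single values carry no SD here, and depth is unknown.

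The most strongly risen row not annotated as protein-coding was a different one in each of the 4 comparisons. In the authors' deposited table the lincRNA RP11-71N10.1 (chromosome 3, 147657714 to 147724914, hg19) had a mean normalised count of 4.51 in control and 1285 in the libraries titled trex5008, with a log2 fold change of 5.56. The lincRNA AC116609.2 (chromosome 2, 739816 to 751712) went from 162.5 to 3908 in the libraries titled trex8168 in the authors' deposited table, a log2 fold change of 4.23. The locus XLOC_035785 (chromosome 2, 56180865 to 56276825), which has no annotated type, went from 12.2 to 491.9 in trex4039 in the authors' deposited table, with a log2 fold change of 3.75 and an adjusted p of 1.6e-169. The antisense RNA CTD-2201G16.1 (chromosome 14, 23871736 to 23889217) went from 3.40 to 796.6 in trex0108 in the authors' deposited table, a log2 fold change of 4.97. The authors' deposited table lists the adjusted p of RP11-71N10.1, AC116609.2 and CTD-2201G16.1 in these comparisons as 0. Among these 4 rows in the other comparisons, AC116609.2 in trex4039 alone passed the threshold, with a log2 fold change of 0.89 and an adjusted p of 5.06e-20 in the authors' deposited table. Other unannotated loci rose too, such as CATG00000005887.1 from 0.616 to 392.9 in trex0108 and CATG00000013615.1 from 0.616 to 119.3 in trex8168 in the authors' deposited table. These rows were singled out after their values were seen, and the table does not say which row is the targeted RNA, so the conflict between titles and target labels stays open.

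**Figure D1:**
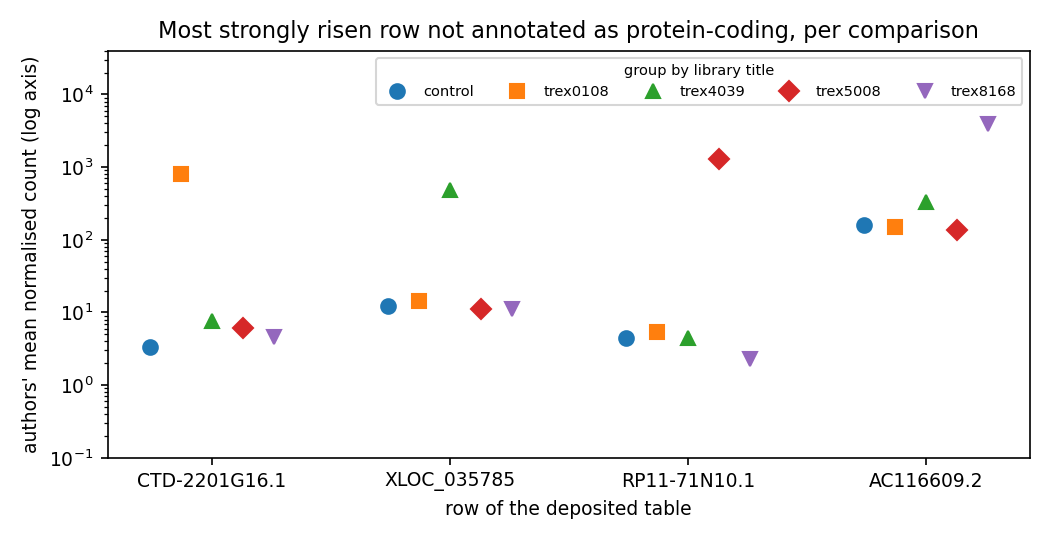
The deposited mean normalised count (log axis) of 4 rows in the 5 groups, 1 point per group mean, with no error available. Each row stands highest in 1 group: CTD-2201G16.1 at 796.6 in trex0108, XLOC_035785 at 491.9 in trex4039, RP11-71N10.1 at 1285 in trex5008 and AC116609.2 at 3908 in trex8168.

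In the trex0108 comparison the changes were nearly all rises, and RUFY4, AGXT and MYH6 led those of protein-coding genes. RUFY4 went from a mean of 41.5 to 4548, with a log2 fold change of 5.23 in the authors' deposited table. AGXT, a liver peroxisomal aminotransferase, went from 1.56 to 422.2, and MYH6, the cardiac alpha myosin heavy chain, from 50.1 to 1184 in the authors' deposited table. The serine protease KLK7, the WNT ligand gene WNT8A, BZRAP1 and TMEM190 rose with log2 fold changes of 3.42, 3.04, 2.98 and 2.14 in the authors' deposited table. The falls among named genes with a mean of at least 50 were small on the shrunken scale: the authors' deposited table gives log2 fold changes of -0.47 for RP11-763B22.7 and KIF12, -0.45 for WFIKKN2, -0.44 for KIAA1324 and -0.35 for CYBRD1 and RP4-665J23.1, followed by RP11-245P10.4 at -0.34 and MEGF6 at -0.31. At an adjusted p under 0.05 in the authors' deposited table, 634 rows were higher and 28 lower, of which 411 and 17 were protein-coding. With a log2 fold change of at least 1 in size, 99 rows were higher and 0 lower, and by the log2 ratio of means 235 called rows were higher and 2 lower by at least 1. Below a mean of 50, ABR and UVSSA stood at 41.6% and 48.3% of control in trex0108 by the means in the authors' deposited table. Among the risen rows 189 (29.8%) had a control mean under 50.

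Around CTD-2201G16.1 several genes rose together in trex0108. Of 11 other listed rows within 500 kb, 5 were higher and 0 lower. MYH6 overlaps CTD-2201G16.1, and reads of the pair cannot be fully told apart without the strand setting of the counting. ZFHX2 (chromosome 14, 23984327 to 24025146) rose with a log2 fold change of 0.32 and an adjusted p of 0.00855 in the authors' deposited table, and CATG00000018307.1 rose with 0.55. Farther out, CEBPE, a myeloid transcription factor gene, went from 4.63 to 146.8 and the amino acid transporter gene SLC7A8 from 2114 to 3112 in the authors' deposited table; both were named after their values were seen. Of the 5 nearest rows, XLOC_019262 and XLOC_019268 had log2 fold changes of -0.04 and -0.07 and were not called in the authors' deposited table.

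**Figure D2:**
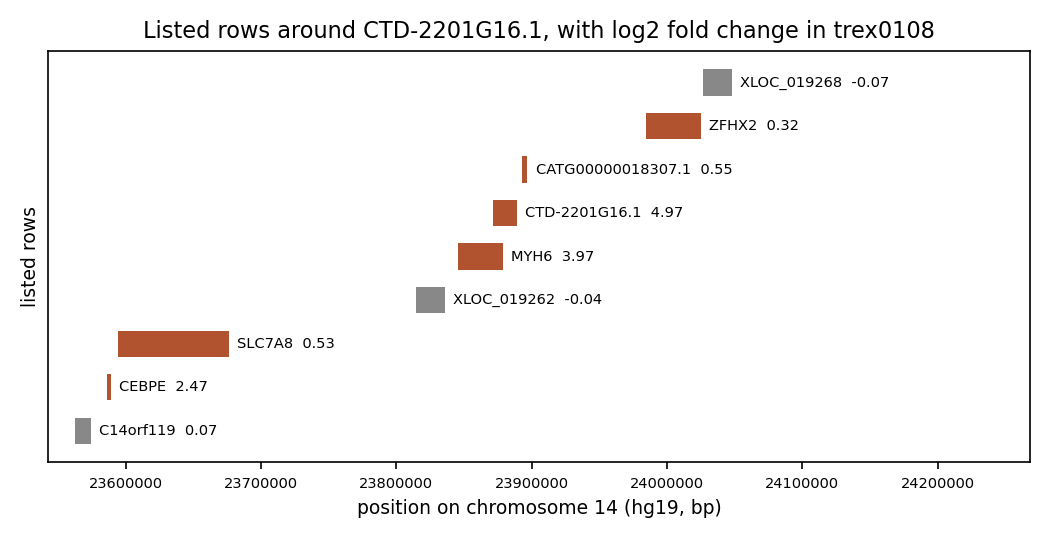
Map of the listed rows around CTD-2201G16.1 on chromosome 14 (hg19, bp), 1 bar per row drawn to scale with its deposited log2 fold change in trex0108. Rust bars were called higher at an adjusted p under 0.05 and grey bars were not called; MYH6 (3.97) and CTD-2201G16.1 (4.97) overlap.

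None of 24 tested gene lists passed an adjusted p of 0.05 in trex0108 (cameraPR, adjusted p from 0.128, for immediate early genes, to 0.991; 1 list had an unadjusted p under 0.05). Of the 8 listed immediate early genes 3 rose and 0 fell: EGR1, EGR2 and EGR3, zinc finger transcription factors, with log2 fold changes of 0.98, 0.50 and 0.40 in the authors' deposited table. Of 6 listed genes of cortical hem, choroid plexus and neural crest, BMP4 alone was called, with a log2 fold change of 1.39 and an adjusted p of 4.01e-71 in the authors' deposited table. Among members with a mean of at least 50, both lists passed with an adjusted p of 0.0222, and with signed log10 of the adjusted p the cortical hem list passed with 0.0324 (cameraPR). These members were named after their values were seen.

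**Figure D3:**
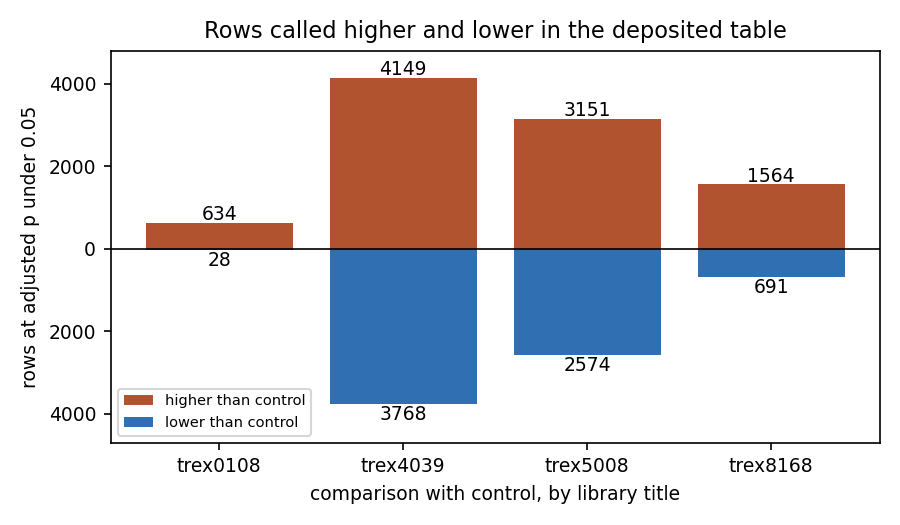
Rows higher (rust) and lower (blue) than control at a deposited adjusted p under 0.05, by library title. The trex0108 bars are nearly one-sided (634 and 28), and the trex4039 bars are the tallest in both directions (4149 and 3768).

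The trex4039 comparison had the most calls, nearly all of small size. LENG8, the furthest fallen named gene by deposited log2 fold change, went from a mean of 10500 to 4363, with a log2 fold change of -1.19 and an adjusted p of 7.64e-66 in the authors' deposited table. The antisense RNAs ASMTL-AS1 and CTD-3184A7.4, SSPO, NBEAL2, the DNA glycosylase gene MPG, CPNE7 and the perlecan gene HSPG2 fell with log2 fold changes from -1.11 to -0.96 in the authors' deposited table. The named rises were led by PKLR, a pyruvate kinase of liver and red cells, with means of 403.6 and 1320 and a log2 fold change of 0.89 in the authors' deposited table. GULP1, NXT2, CAP2, the tumour suppressor gene RB1, the spliceosomal RNA gene RNU5E-1 and GMFB rose with 0.73, 0.71, 0.70, 0.66, 0.65 and 0.65 in the authors' deposited table; with the GC trend removed, GULP1 and GMFB stood at 0.30 and 0.27. In all, 4149 rows were higher and 3768 lower at an adjusted p under 0.05 in the authors' deposited table, with a median size of 0.31 on the log2 scale, and 16 rows reached a size of 1, of which 1 was higher and 15 lower. By the log2 ratio of means, 68 called rows were higher and 553 lower by at least 1. Of the called protein-coding genes with a GC content, 2728 were higher and 1882 lower, and 341 and 662 of them (21.8% in all) kept their direction and at least 0.5 of their size with the GC trend removed.

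Within 500 kb of XLOC_035785, 3 of 4 listed rows were higher and 1 lower in trex4039. PNPT1, a mitochondrial RNA-degrading enzyme gene, and CCDC104 rose with 0.27 and 0.32, XLOC_035780 rose with 0.29, and the antisense RNA RP11-554J4.1 fell to -0.38 on the log2 scale in the authors' deposited table. In trex5008, where XLOC_035785 was not called, PNPT1, CCDC104 and XLOC_035780 also rose, with 0.25, 0.28 and 0.24 in the authors' deposited table. The nearest of these rows ends more than 100 kb away, and 0 rows were listed within 100 kb.

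None of the 24 lists passed in trex4039 (cameraPR, adjusted p from 0.083 to 0.998; 5 lists had an unadjusted p under 0.05 and share the lowest value). Those lists were radial glia (0 higher and 7 lower of 9 listed), immediate early genes (0 and 3 of 8), YAP/TEAD targets (3 and 0 of 3), NOTCH targets (0 and 4 of 5) and extracellular matrix (3 and 10 of 14). Named after their values were seen, CYR61, CTGF and ANKRD1, targets of the YAP/TEAD pathway, rose with 0.47, 0.44 and 0.38 in the authors' deposited table. MYC and JUN fell with log2 fold changes of -0.77 and -0.59, and HES5, a NOTCH-responsive repressor gene, with -0.96 in the authors' deposited table. With signed log10 of the adjusted p, immediate early genes passed as lower (cameraPR, 0.0168). On the rows with a transcript GC content alone, radial glia passed with 0.0226, and immediate early genes, NOTCH and extracellular matrix with 0.0287 each (cameraPR). With the GC trend of these rows also removed, NOTCH and extracellular matrix passed with 0.0462 and 0.0311 and YAP/TEAD, at 0.109 before, with 0.0269, while radial glia and immediate early genes did not pass, with 0.0781 and 0.0552 (cameraPR). The cytosolic ribosomal protein list (0 higher and 5 lower of 18) then passed as lower with 0.0311, from 0.365, although its deposited median was 0.03 and its mean -0.08 on the log2 scale.

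In the trex5008 comparison, lists of NOTCH targets, TGF-beta and BMP targets and extracellular matrix passed as lower and heat shock genes as higher with the fold change as the statistic. None did with signed log10 of the adjusted p (cameraPR, adjusted p from 0.2 to 0.343). RP11-71N10.1, with an adjusted p listed as 0, enters that statistic at its cap and can widen the spread the test uses. Whether this accounts for the lost calls was not tested. HES5 went from a mean of 245.8 to 133.3, with a log2 fold change of -0.72, and HES1 and NRARP fell with -0.45 and -0.19 in the authors' deposited table. Of 5 listed NOTCH targets 3 fell and 0 rose (cameraPR, adjusted p 0.0132). Of 7 listed TGF-beta and BMP targets 6 fell and 0 rose (cameraPR, adjusted p 0.0147), led by SMAD6, ID3 and ID1 at -0.50, -0.37 and -0.31 in the authors' deposited table. Of 14 listed rows of extracellular matrix genes 8 fell and 0 rose (cameraPR, adjusted p 0.0132), among them the collagen genes COL5A1, COL4A2 and COL6A2 at -0.40, -0.35 and -0.33 in the authors' deposited table. With the GC trend removed these 3 stood at -0.19, -0.11 and -0.04, ID1 at -0.12 and NRARP at 0.11. The median of the extracellular matrix list then went from -0.26 to -0.12, and all 3 lower lists still passed (cameraPR, adjusted p 9.14e-04 for extracellular matrix and 0.00254 for the others).

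Of 9 listed rows of radial glia genes 5 fell and 0 rose in trex5008 (cameraPR, adjusted p 0.0132), and the members that fell most were HES5, NOTCH1 at -0.49 and HES1 in the authors' deposited table, of which HES5 and HES1 also stand in the NOTCH list. For cortical hem, choroid plexus and neural crest, 3 of 6 fell and 0 rose (cameraPR, adjusted p 0.0147): FOXD3, WNT3A and BMP4 at -0.42, -0.38 and -0.28 in the authors' deposited table. This list did not pass among members with a mean of at least 50 (cameraPR, adjusted p 0.147), and without the GC trend FOXD3, WNT3A and BMP4 stood at -0.16, -0.09 and -0.18. Among heat shock genes 7 of 8 rose and 0 fell (cameraPR, adjusted p 0.0147), with the chaperone genes DNAJA1, CACYBP and CHORDC1 at 0.37, 0.34 and 0.32 in the authors' deposited table. All cells, control included, received an activator with an HSF1 part. With the GC trend removed, the heat shock and cortical hem lists no longer passed, with adjusted p of 0.097 and 0.197 (cameraPR), and DNAJA1, CACYBP and CHORDC1 stood at 0.19, 0.14 and 0.10. The radial glia list still passed (cameraPR, adjusted p 0.0366), with its median from -0.24 to -0.12 and NOTCH1 at -0.24. The radial glia and cortical hem lists did not pass with signed log10 of the adjusted p either (cameraPR, 0.343 and 0.777). The other 18 lists had adjusted p from 0.153 to 0.958 (cameraPR).

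PKLR and RNU5E-1 were among the named rises, and LENG8, CTD-3184A7.4, NBEAL2, HSPG2 and SSPO among the named falls, of both trex5008 and trex4039. Besides RP11-71N10.1, the named rises were PKLR at 0.84, RNU5E-1 at 0.66, AC010468.1 at 0.65, the potassium channel gene KCNA1 at 0.63, ANKRD37 at 0.56, FTH1P11 at 0.55 and the transcription factor gene POU2F1 at 0.54 in the authors' deposited table. By deposited log2 fold change, LENG8 fell most among named genes with a mean of at least 50, to -0.81. It was followed by CTD-3184A7.4, NBEAL2, RP5-882C2.2, HSPG2, the transcription factor gene TEF, SSPO and CTD-3193O13.9, with values from -0.80 to -0.73 in the authors' deposited table. At an adjusted p under 0.05 in the authors' deposited table, 3151 rows were higher and 2574 lower, and 2 of them reached a size of 1 on the log2 scale. By the log2 ratio of means, 17 called rows were higher and 34 lower by at least 1. Of the called protein-coding genes with a GC content, 2048 were higher and 1457 lower, of which 330 and 361 (19.7% in all) kept direction and at least 0.5 of their size without the GC trend. No row was listed within 500 kb of RP11-71N10.1, so its neighbours give no value.

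In the trex8168 comparison, GFRA2, SCNN1A and S100A4 led the named rises after AC116609.2. GFRA2, a receptor of the GDNF family, went from a mean of 189.6 to 640.8, and SCNN1A, a subunit of the epithelial sodium channel, from 68.3 to 254.9 in the authors' deposited table, with log2 fold changes of 1.53 and 1.45. The calcium-binding protein gene S100A4, PAMR1, FAM131B, the cadherin gene FAT3 and CSDC2 rose with 1.10, 0.89, 0.85, 0.83 and 0.80 in the authors' deposited table. The named falls were XXbac-B562F10.11, WFIKKN2, ASMTL-AS1 and MPG, from -0.75 to -0.71, and LINC00085, TPPP, RP11-282I1.1 and RP11-245P10.4, from -0.62 to -0.59 in the authors' deposited table. At an adjusted p under 0.05 in the authors' deposited table, higher rows numbered 1564 and lower rows 691, and 10 reached a size of 1, all of them higher. By the log2 ratio of means, which is not shrunken, 19 called rows were higher and 88 lower by at least 1.

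Of 18 listed cytosolic ribosomal protein genes, 5 rose and 0 fell in trex8168, and the list passed (cameraPR, adjusted p 0.0415). RPS14, RPS25 and RPL6 rose with 0.24, 0.23 and 0.22 in the authors' deposited table, each with an adjusted p between 0.01 and 0.05. The list did not pass on the rows with a GC content, with the trend kept or removed (cameraPR, adjusted p 0.0679 and 0.163), or with signed log10 of the adjusted p (0.97). The other 23 lists did not pass, with adjusted p from 0.053 to 0.949 (cameraPR). Lists with fewer than 3 listed rows were not tested in any comparison: pluripotent stem cells (1), replication-dependent histones (2) and mitochondrially encoded genes (0). Within 500 kb of AC116609.2 only AC116614.1 and XLOC_032422 were listed, at 0.04 and 0.19 on the log2 scale with adjusted p of 0.899 and 0.0542 in the authors' deposited table.

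Called alike in all 4 comparisons were 30 rows that rose and 8 that fell. Simulated groups without changes, against shared controls and with the observed numbers of calls imposed, gave 196.5 and 11.96 such rows. These values, added after the data were seen, are not what shared controls alone would yield. Independent lists over the listed rows would give 9.33 and 0.143. Among the genes named for this, the rises were LOH12CR2, EIF4HP1, RAB7L1, a small GTPase gene, and the secretogranin gene SCG3, and the falls were UVSSA, WFIKKN2, ABR and RP11-245P10.4. WFIKKN2 had log2 fold changes of -0.45, -0.37, -0.60 and -0.74 in trex0108, trex4039, trex5008 and trex8168 in the authors' deposited table, and SCG3 had 0.32, 0.40, 0.46 and 0.29.

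Rows tested in both trex4039 and trex5008 were higher in both for 2695 and lower in both for 2165, with 6 opposite. Independent lists of these sizes would share 1221 and 851. Simulated groups without changes, against shared controls and with the observed numbers of calls imposed, shared 1975 and 1516. The Spearman correlation of the fold changes across listed rows was 0.861, against a correlation of 0.5 simulated for unchanged groups; rows are not independent replicates. Over rows with a GC content it was 0.855, and 0.628 with the GC trend removed. For trex5008 and trex8168 the Spearman correlation was 0.633 over listed rows, 0.615 over rows with a GC content and 0.626 with the trend removed. For trex4039 and trex8168 it was 0.614, 0.553 and 0.521. Without the trend, trex4039 and trex5008 were thus about as alike as trex5008 and trex8168. Pairs with trex0108 had from 0.390 to 0.424 without it. For trex4039 and trex8168 the shared counts were 992 and 558, with 78 opposite, and with 1108 and 505 simulated and 600 and 230 for independent lists. For trex5008 and trex8168 they were 954 and 415, with 38 opposite, and with 951 and 421 simulated and 465 and 164 for independent lists. The trex0108 comparison shared 151 rises and 20 falls with trex4039 and 61 and 9 with trex8168, with 474 and 25.1, and 271 and 14.1 simulated. Independent lists would give 225 and 9.42, and 81.1 and 1.81. All values for independent lists rest on the listed rows alone, which raises them. Shared rises below them therefore do not show fewer shared calls than independent responses would give. Opposite calls numbered 78 with trex4039 and 14 with trex8168. With trex5008 it shared 124 calls in the same direction, and 87 were opposite; simulation gave 389 shared rises and 23.1 falls, and independent lists 163 and 6.81. Controls of 3 libraries cannot be split, so part of each overlap may come from the shared controls. Contrasts that share no library, trex4039 over trex0108 and trex5008 over control, correlated across rows with a Spearman rho of 0.772, and trex5008 over trex0108 with trex4039 over control gave 0.623. For the pairs with trex8168 such contrasts gave 0.538 and 0.284 (trex4039) and 0.424 and 0.318 (trex5008). Contrasts of this kind were not repeated with the GC trend removed. For the pairs with trex0108 they gave -0.623 and 0.408 (trex4039), -0.772 and -0.408 (trex5008) and -0.538 and -0.435 (trex8168), while the correlations with shared controls were 0.583, 0.566 and 0.522. The reference group in place of control was trex5008 for the pair with trex4039, and trex4039 for the other pairs. Thus -0.623, -0.772 and -0.538 are the values 0.623, 0.772 and 0.538 above with the ratio inverted, and 0.408 and -0.408 mirror each other likewise. They are no separate evidence of opposite responses in trex0108.

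Over all listed rows, the covariance of log2 fold changes was 0.0629 for trex4039 and trex5008, 0.0359 for trex4039 and trex8168 and 0.0246 for trex5008 and trex8168. For trex0108 it was 0.0212 with trex4039, 0.013 with trex5008 and 0.0111 with trex8168. A value simulated from shared controls alone could be had only for rows called in both comparisons, which are selected for larger changes, and from approximate standard errors. Over those rows the observed and simulated covariances were 0.106 and 0.00291 for trex4039 and trex5008, 0.116 and 0.00346 for trex4039 and trex8168, and 0.0787 and 0.00301 for trex5008 and trex8168. With trex0108 they were 0.00922 and 0.00358 for trex4039, -0.00783 and 0.00328 for trex5008, where the sign differs from that over all rows, and 0.086 and 0.0038 for trex8168. The covariances over called rows were added after the data were seen.

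Some genes called in both comparisons of a pair differed in response, by an approximate test of the difference. The creatine transporter gene SLC6A8 rose in trex0108 and fell in trex4039, with log2 fold changes of 1.32 and -0.18 in the authors' deposited table (approximate adjusted p of the difference 9.1e-85). IRX3, a homeobox gene, had 1.70 in trex0108 and -0.25 in trex4039 in the authors' deposited table (1e-71). SCNN1A had -0.37 in trex5008 and 1.45 in trex8168 in the authors' deposited table (2.56e-18), and the neuronal kinesin gene KIF1A had -0.49 in trex4039 and 0.20 in trex8168 (3.67e-11). These genes were named after their values were seen. For trex4039 and trex5008, 62 of 4866 genes differed with the shared-control covariance set to 0, and 655 with it set to a share of 0.5. With 3 libraries in each group and in control, the share is near 0.5 where their spread is alike. A covariance of 0 thus leaves out a known dependence and gives a low count. The errors are approximate, so the number is not settled.

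Fold changes followed the GC content of transcripts in the trex4039 and trex5008 comparisons. Among 6416 protein-coding genes, those lowest in GC content (30.2% to 40.1%, 1285 genes) had a median log2 fold change of 0.31 in trex4039 and 0.21 in trex5008, while those highest (59.2% to 74.5%, 1283 genes) had -0.30 and -0.24. In trex4039, 1125 of the genes lowest in GC were higher and 17 lower, against 10 and 926 in the highest. The Spearman rho across genes was -0.776 in trex4039, -0.774 in trex5008, -0.394 in trex0108 and -0.277 in trex8168. The R2 of the trend was 0.611 and 0.638 in trex4039 and trex5008, and 0.0126 and 0.0873 in trex0108 and trex8168, for genes with a change under 2 in size. With the trend removed, 1003 of 4610 called genes in trex4039 kept their direction and at least 0.5 of their size, and 34.0% of these were higher, against 59.2% of all called. In trex5008 691 of 3505 did, with 47.8% higher against 58.4%. In trex0108 all 393 did, and in trex8168 1163 of 1342.

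**Figure D4:**
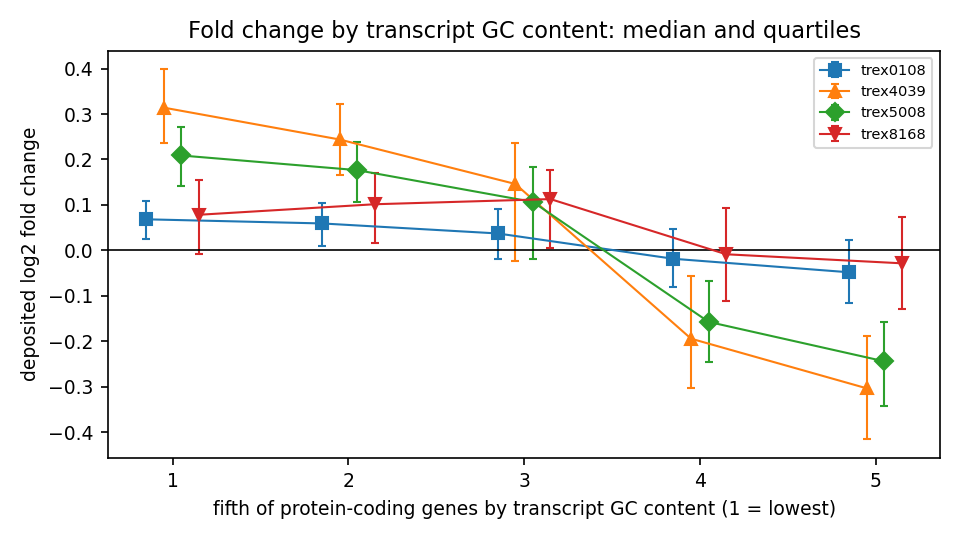
Median deposited log2 fold change of protein-coding genes in 5 groups of rising transcript GC content, with bars from the lower to the upper quartile. The trex4039 medians run from 0.31 to -0.30 and the trex5008 medians from 0.21 to -0.24, while the trex0108 medians stay between 0.07 and -0.05.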

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

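The tests of the one-sided rises in trex0108 and of AC116609.2 in trex4039 were chosen after the result was seen. With the shared-control covariance set to 0, genes called in both comparisons of a pair differed in log2 fold change, by the approximate test, for 48.2% of 249 (trex0108 and trex4039), 47.9% of 211 (trex0108 and trex5008) and 29.8% of 84 (trex0108 and trex8168). The other pairs had 1.27% of 4866 (trex4039 and trex5008), 19.8% of 1628 (trex4039 and trex8168) and 3.91% of 1407 (trex5008 and trex8168). With a share of 0.5, which lies closer to the design, these other pairs had 655, 593 and 136 differing genes, and the pairs with trex0108 also had more. All genes called in opposite directions were among those that differed, in both settings. The approximate errors come from the same adjusted p as the calls, so opposite calls could hardly give another result. Outlying libraries were not sought, since the groups of 3 hold means alone.

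In trex4039 and trex5008, log2 fold changes fell with transcript GC content. A trend that came from the control libraries alone would vanish without them, but the ratio of the trex4039 to the trex0108 mean kept a Spearman rho of -0.710 with GC content. The 21.8% and 19.7% of called genes that kept direction and 0.5 of their size without the trend restate that trend and decide nothing. For a GC bias as the source of the lower lists in trex5008, the bound written beforehand counted at least 80% staying called against it. Exactly 80% (4 of 5) stayed called without the trend, which meets that bound. Medians moved from -0.24 to -0.12 (radial glia), -0.26 to -0.12 (extracellular matrix), -0.33 to -0.17 (cortical hem), -0.29 to -0.21 (TGF-beta and BMP) and -0.19 to -0.24 (NOTCH, which shares HES1 and HES5 with radial glia). A part played by GC bias in these lists therefore stays open. A GC-dependent library bias of the whole pattern stays open too: over 23 chromosomes, the median change of rows not annotated as protein-coding followed GC content with a rho of -0.874 in trex4039 and -0.884 in trex5008 (permutation test, p 2e-05, the smallest these permutations can give), but trex0108 gave -0.847, so this test is not specific, and changes of GC-rich and GC-poor genes through the activated RNA or guides acting elsewhere, not tested, would give the same.

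In trex0108, 634 rows were higher and 28 lower. A common scaling factor leaves distances from the median as they are, so by itself it would not make the tails uneven. Among 10869 rows listed through another comparison, 95.3% of the rows far from the median lay above it (121 above, 6 below). The distance used was the median size of the trex0108 calls (0.449), and the median of these rows was 0.016. The uneven tails thus largely restate the one-sided calls and are no separate evidence against scaling. A GC bias like that of trex4039 is argued against by risen genes having a median GC content 5.64 percentage points above the other listed genes. Spread of activation from a few loci may account for part: 25.9% of risen genes (164 of 634) lay within 50 kb of another risen gene, against 11.4% in random draws, more than in any of 100 draws. That share lies between both bounds set for it, which keeps this explanation open. An effect of the activated RNA, or of guides acting at other promoters, was not tested.

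AC116609.2, the strongest rise in trex8168, was also higher in trex4039. RNA or reads carried over from the trex8168 libraries could give this, and AC116609.2 showed 4.50% of its trex8168 excess in trex4039. The 9 other genes that rose most in trex8168 had a median of 6.05%, but from -3.73% to 20.8%, with 5 of 9 above 0. By the bound first written the median alone would have counted for carry-over, and the rule was tightened after these values were seen, since members that go both ways decide nothing. Carry-over and a response of the gene in trex4039 therefore cannot be told apart.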

How the results depend on the processing

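Settings chosen after seeing the data were the ratio of means, protein-coding rows, single rows per symbol, rows with a GC content, GC removal, the signed log10 p, the contrasts without shared libraries and the highest locus number; the others were planned. With a log2 fold change of at least 1, the genes changed were 99 (trex0108), 16 (trex4039), 2 (trex5008) and 10 (trex8168), and a log2 ratio of means of at least 1 was met by 35.8%, 7.84%, 0.891% and 4.75% of the called genes. Protein-coding genes numbered 428 in trex0108, and 976 genes passed 0.01 in trex8168. GC removal left 1003 genes in trex4039 and 691 in trex5008. Stricter thresholds pass fewer genes by construction; for the other settings the cause was not tested.

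Calls shared in direction at 0.01 were 94, 54 and 27 for trex0108 with trex4039, trex5008 and trex8168, 676 for trex4039 and trex8168, and 584 for trex5008 and trex8168. With a log2 size of at least 1, 1 was shared by trex4039 and trex5008 and 0 by every other pair. With a shared-control variance of 0.5 of the squared standard error, 655 genes differed between trex4039 and trex5008 (140 with the highest locus number), 593 between trex4039 and trex8168 and 136 between trex5008 and trex8168. Within 100 kb, 3 neighbours were called in trex0108 and 0 in trex4039, and within 1 Mb 7 in trex4039 and 1 in trex5008.

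Adjusted p of lists crossed 0.05 as follows. For members with a mean of at least 50, cortical hem and immediate early genes reached 0.0222 in trex0108, and cortical hem lost its call in trex5008 (0.147). With signed log10 p, cortical hem reached 0.0324 in trex0108 and immediate early genes 0.0168 in trex4039, while in trex5008 radial glia and NOTCH targets gave 0.343, cortical hem 0.777, and heat shock, TGF-beta and extracellular matrix 0.2005; ribosomal proteins gave 0.97 in trex8168. On rows with a GC content, trend kept, trex4039 gained radial glia (0.0226) and immediate early genes, NOTCH and extracellular matrix (0.0287 each), and trex8168 lost ribosomal proteins (0.0679), so these shifts need no GC removal. With GC removed, trex4039 gained YAP/TEAD (0.0269), NOTCH (0.0462), extracellular matrix (0.0311) and ribosomal proteins (0.0311), trex5008 lost cortical hem (0.197) and heat shock (0.097), and trex8168 lost ribosomal proteins (0.163). Of named gene values, GC removal more than halved 11 and reversed 1, NRARP in trex5008 (to 0.11); COL6A2, WNT3A and COL4A2 in trex5008 then stood at -0.04, -0.09 and -0.11. The ratio of means moved 11, all to larger size, and 9 were not called at 0.01. A list counted as reversed only where a call was made in either setting.

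No list called with the deposited fold change passed with the signed log10 p. The list calls thus depend on the statistic used. RP11-71N10.1 in trex5008 and AC116609.2 in trex8168, with an adjusted p listed as 0, enter the signed log10 p at its cap. Such values can widen the spread the test uses, but the lists were not tested without these rows. In trex0108, RUFY4 and CTD-2201G16.1 also enter at the cap, and the cortical hem list passed there with this statistic. The cap is therefore not shown to be the reason. A fold change over the approximate standard errors, nearer to the plan, was not tried for the lists. No paired analysis was possible because the columns hold group means, so replicate numbers carry no values. For the same reason other normalizations, tests, filters and pseudocounts per library, replicates left out, other splits of the samples, an estimated correlation and recomputed adjusted p were planned but not run. Depth is unknown, so no limit from it can be given.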

Other observations

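The tests of gene types, of symbol families and of chromosomes were chosen after the data were seen. Called antisense RNAs were lower more often than called protein-coding genes in 3 comparisons: 158 lower and 50 higher in trex4039 (Fisher's exact test, two-sided, odds ratio 0.235, adjusted p 1.52e-20), 80 and 27 in trex5008 (odds ratio 0.256, 4.02e-10) and 35 and 15 in trex8168 (odds ratio 0.118, 7.76e-12). Called lincRNAs were lower more often too, with 74 lower and 36 higher in trex4039, 40 and 16 in trex5008 and 17 and 9 in trex8168. In trex8168 so were processed transcripts (10 lower and 1 higher, Fisher's exact test, adjusted p 5.69e-06) and pseudogenes (34 and 28, 9.98e-08), so every type tested there differed from protein-coding genes. Processed transcripts were also lower more often in trex4039 (23 and 12, Fisher's exact test, adjusted p 0.0162), while pseudogenes were not called there (0.691). In trex0108, 32 antisense RNAs were higher and 2 lower, and no difference from protein-coding genes was called (adjusted p 0.691). These counts are not corrected for GC content or for expression level.

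Among 32 families of gene symbols, collagen genes (COL) were lower in trex4039 (14 lower and 1 higher of 19, cameraPR adjusted p 0.0109) and in trex5008 (12 and 0, 0.00112). With the GC trend removed, which also leaves out rows without a GC content, these had 0.463 and 0.0555. Zinc finger genes (ZNF) were higher in trex4039 (78 higher and 28 lower of 148, cameraPR adjusted p 0.0404), with 0.898 after GC removal. Genes of mitochondrial ribosomal proteins (MRPL) and of the large cytosolic ribosomal subunit (RPL) were higher in trex8168 (14 and 0 of 25, and 6 and 0 of 15, both 0.00831), with 0.00627 and 0.0165 after GC removal. In trex5008 they passed as higher only after GC removal (cameraPR adjusted p 4e-04 and 0.0114, from 0.226 and 0.113), and zinc finger genes then passed as lower in trex8168 (0.014, from 0.38). On chromosome 19, 8.65% of listed rows rose in trex0108 against 5.41% elsewhere (Fisher's exact test, adjusted p 9.79e-04), and on chromosome 16 2.81% did against 5.79% (adjusted p 0.00772). In the other comparisons chromosome 19 had fewer rises than elsewhere: 11.1% against 39.0% in trex4039 (adjusted p 2.8e-65), 5.48% against 29.8% in trex5008 (1.23e-63) and 6.70% against 14.5% in trex8168 (1.26e-10). Chromosome 16 had 17.1% against 37.9% in trex4039 (2.13e-23) and 12.9% against 28.8% in trex5008 (1.92e-16). Of 23 chromosomes, 2 were called in trex0108, 17 in trex4039, 16 in trex5008 and 1 in trex8168, without correction for GC content. The mitochondrial locus held 11.1% of the summed means of listed rows in control and 11.98% in trex8168.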
